A study of Mus musculus with 2 samples.

How the data were processed

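RNA was measured in LSK cells (lineage-low or -negative, Sca1-positive, c-Kit-high) of C57BL/6 mice with an orthotopic liver tumour, for which, per the labels, Hepa1-6 cells were injected into the left liver lobe. Cells of the bone marrow and of the spleen each gave 1 library of the Chromium 3′ assay. The extract protocol says that lineage-depleted or c-Kit-positive cells were enriched on magnetic beads before the flow sort, without saying which step was used for which tissue. The number of mice behind each library is not stated.

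The deposited count files hold counts: UMI counts of 31053 genes (Ensembl identifiers) per cell, whole numbers that carry no normalization. Per the series design text, the authors aligned about 27000 reads per cell to mm10 and counted them with Cell Ranger 3.1.0. The processing notes of the samples list Seurat 3.1.5 and the genome build mm9, which conflicts with the design text, and the kit is version 3 in the design text and version 3.1 in the extract protocol. The filter on cells and the treatment of doublets are not stated; the deposited cells had at least 513 (bone marrow) and 503 (spleen) genes and at most 9.42% and 9.08% mitochondrial UMIs. The deposited cell table gives, for the same cells, library, cluster, 2 sets of reference labels, and columns whose unit is a score: stemness, myeloid, erythroid and ER stress scores, pseudotime, size factor and the total of the SCT assay. How the authors made each score, and from which genes, is not stated. A column named for the GO term of the response to ER stress was compared with the ER stress score only and held the same value in all cells. The column nFeature_SCT and the 3 UMAP coordinates were not used. The integrated, normalized matrix was left out because batch-integrated values are not expression.

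Gene symbols and coordinates were taken from the GENCODE M21 annotation (mm10) by Ensembl identifier; 31011 of the identifiers were paired with a symbol. For a symbol on more than 1 identifier (35 symbols), the identifier with more UMIs was used, which concerns Ddit3. All deposited cells were kept. Counts were summed over the cells of each library, or of each cluster within a library, and scaled to CPM, the same total over all genes in each sum. Each sum has an exact Poisson interval, a ratio of sums has the exact interval of 2 Poisson counts, and shares of cells have exact Clopper-Pearson intervals, all at 95% and for counting error only. A count of 0 was read as allowing 3 counts, or for cells the upper exact bound. No fold was computed against 3 or fewer UMIs. The log2 ratio was (spleen CPM + 1) over (bone marrow CPM + 1) among genes with a mean of at least 10 CPM over both libraries. With 1 library per group, no test was run and cells were not treated as replicates; genes are described by size alone, at least 2-fold higher or lower.

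A set of 31 gene lists covered the unfolded protein response, lineage programmes, cell state and stress responses, the cell cycle, the sort gate, and markers of other cell types. A list member counts as higher or lower at 1.5-fold. A list median has its 95% range over 1000 resamplings of its members and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins; lists with fewer than 4 measured members are given by their members. The composition-matched value weights the CPM of each of the authors' 8 clusters by the mean of its shares in both libraries. Within clusters, lists were read where each library had at least 100 cells, which leaves out MCP.

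The genes named follow a rule: the 12 highest and 12 lowest log2 ratios over all cells among genes with at least 50 CPM in 1 or both libraries, without gene models named Gm or ending in Rik; of each list, the 2 highest and 2 lowest measured members; always Eif2ak3, Ern1, Atf6, Atf4, Ddit3, Xbp1, Hspa5, Calr, Kit, Ly6a, Cebpa, Cebpb, Spi1, Mpo, Elane, Procr, Hlf, Flt3, Dntt, Gata1, Pf4 and Mki67; and in each cluster the 3 highest and 3 lowest by the same limits. Ciita, Slc7a5 and Ppp1r15a, and leading genes of clusters, were named after their values were seen. A few genes that the rule names are not reported here. The gene lists, cell type markers, size limits, the rule for named genes and most alternatives were set before the data were examined.

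For comparisons at equal depth, each cell was thinned at random to 3700 UMIs, the 10th percentile of UMIs per cell in the bone marrow library rounded down; 1007 bone marrow and 672 spleen cells below that depth were left out. Median genes per cell were 2403 and 3028.5 as deposited and 1718 and 1637 after thinning. Cell cycle phases were called on thinned cells with the scanpy function score_genes_cell_cycle. Both libraries were clustered together in scanpy on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 0.8 (0.4 and 1.2 as alternatives), and clusters were named by the cell type with the most fixed markers, at least 3, among 50 leading genes. The score of the unfolded protein response lists was the scanpy gene score on log values after scaling each library to its own median depth, both to a total of 10000, or after thinning. Scrublet called 185 spleen cells doublets (2.83%) but 2 of 10088 bone marrow cells (0.0198%); whether doublets had been removed before deposit or the calls failed in the bone marrow was not tested.

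Alternatives were TMM factors, a total without mitochondrial, ribosomal protein and the 50 most abundant genes, centring on the median gene, the mean over cells, a stricter cell filter (1000 UMIs, 10% mitochondrial UMIs, the 99th percentile of UMIs), removal of Scrublet doublets, thinning, pseudocounts of 0.1 and 5 CPM, floors of 1 and 50 CPM, removal of cluster MP, and clusters weighted alike. Chosen after seeing the data were the removal of MP and MCP together, the removal of all cells in Leiden clusters with dendritic, T, B or mast cell markers, and the restriction of HSC-1 to cells also labelled HSC-1 in the authors' second annotation. The ratios were tested on simulated data: Poisson counts drawn from the bone marrow profile at the depths of both libraries, with 200 genes changed 3-fold, 100 each way. Of the genes made higher, 100% passed the 2-fold rule, and of those made lower, 87%, since some fell under the floor of 10 CPM. Of the unchanged genes 0 passed, and 3.50% of 200 unchanged lists fell outside the central 95% of random lists. The simulated counts carry no variation between libraries, mice or cells, so they give no rate of false calls in the data. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.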

Results

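Hematopoietic stem and progenitor cells were profiled by droplet single-cell RNA sequencing in C57BL/6 mice that carried an orthotopic liver tumour, grown from Hepa1-6 cells, a mouse hepatoma line. Lineage-low or -negative, Sca1-positive, c-Kit-high cells (LSK cells), the sort gate that holds blood stem cells and the earliest multipotent progenitors, were taken from the bone marrow and from the spleen. The bone marrow library held 10088 cells and 73740963 unique molecular identifiers (UMIs), with a median of 5991 UMIs per cell (770 to 32029). The spleen library held 6546 cells and 85937174 UMIs, with a median of 9978 UMIs per cell (644 to 89330). There was 1 library per tissue, so no difference below was checked against replicates, no test was run, and all intervals (95%) cover counting error alone. Tissue, sort and library preparation differ together between the 2 libraries. No mice without a tumour were analysed here, so each comparison sets spleen against bone marrow within tumour-bearing mice.

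The first question was which kinds of progenitor make up the LSK gate in each tissue. In the bone marrow, the largest cluster was led by stem cell genes. In the spleen, erythroid progenitors, cells with antigen-presenting genes and cells with mast cell proteases took a far larger part. The authors' deposited cell table puts every cell in 1 of 8 clusters, whose abbreviations it does not define, so each is described here by its leading genes. Cluster HSC-1 was led by Hlf, Mecom and Procr, which mark long-term stem cells, and held 50.0% of bone marrow cells (exact Clopper-Pearson interval 49.1 to 51.0%) against 23.5% of spleen cells (22.5 to 24.6%). Cluster HSC-2 was led by the neutrophil granule genes Elane, Mpo and Ctsg with the platelet gene Pf4, and held 21.3% (20.5 to 22.1%) against 11.3% (10.5 to 12.1%). Cluster HSC-3, led by replication-dependent histone genes, held 12.2% against 6.39%. Cluster MEP was led by Car1, Klf1 and Ermap, genes of the early red cell lineage, and held 3.54% (3.19 to 3.92%) against 13.6% (12.8 to 14.5%). Cluster MP was led by Cd74, H2-Aa and Irf8, genes of antigen-presenting cells, and held 1.17% (0.969 to 1.40%) against 21.6% (20.6 to 22.6%), a share 18.5 times as large. Cluster MCP was led by Cma1, Cpa3 and Gzmb, genes of mast cells and basophils, and held 36 cells (0.357%, 0.250 to 0.494%) against 553 cells (8.45%, 7.79 to 9.15%). Cluster LP was led by Ly6d, Dntt and Trbc1, genes of lymphoid and T-lineage cells, in the spleen. In the bone marrow it was led by Dntt, Cmah and Ighm, without Ly6d or Trbc1 among its 50 leading genes. LP held 7.63% of bone marrow cells against 10.6% of spleen cells. Cluster DCP, led by the mitotic genes Cenpf and Ube2c, held 3.75% against 4.61%. Depth differed between clusters as well as between libraries: spleen MEP cells had a median of 36084 UMIs and gave 36.8% of all spleen UMIs, against a median of 11230 and 5.69% in the bone marrow.

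**Figure D1:**
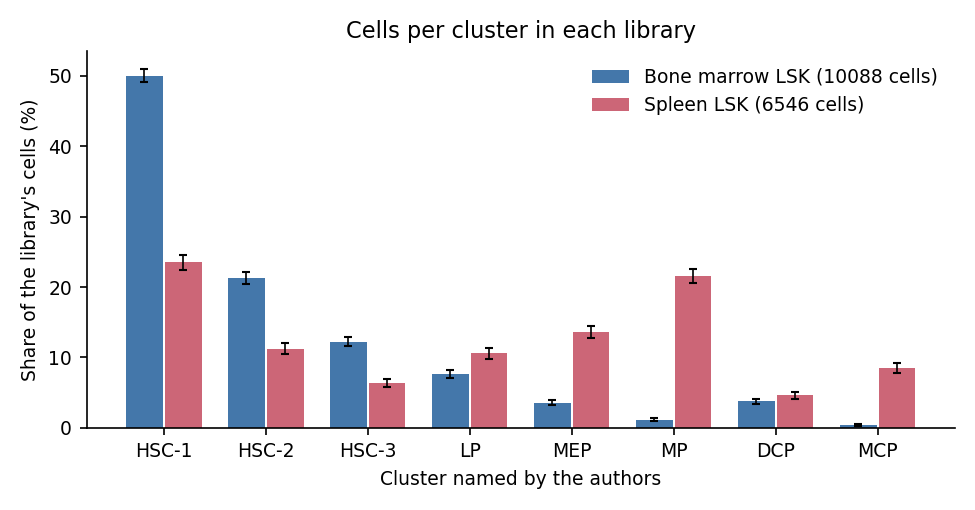
Share of each library's cells (%, y axis) in the 8 clusters named in the authors' table (x axis), with bars for bone marrow LSK (10088 cells) and spleen LSK (6546 cells) and error bars for the exact 95% binomial interval. HSC-1 stands at 50.0% in the bone marrow and 23.5% in the spleen, and MP at 1.17% and 21.6%.

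The deposited clusters did not hold the same mixture of cells in both tissues. Leiden clustering of both libraries together, with each cluster named by markers fixed beforehand, put 46.1% of bone marrow HSC-1 cells in an HSC-like class (Mecom, Hlf, Procr) and 29.8% in a class called lymphoid-primed progenitor-like by its markers, whose leading genes hold Dntt but also Wfdc17, Ccl3, Ccl4 and Cd33. Of spleen HSC-1 cells, 20.9% were HSC-like and 36.6% multipotent progenitor-like, while 15.1% were dendritic cell-like (H2-Eb1, Cd74, Cxcl9) and 13.3% mast cell or basophil progenitor-like (Gzmb, Cyp11a1). Spleen LP was 92.4% T, NK or innate lymphoid cell-like (Trbc1, Tcf7, Bcl11b, Il7r), where bone marrow LP was 91.0% lymphoid-primed progenitor-like; the T, NK or innate lymphoid clusters also carried lymphoid progenitor markers such as Il7r and Ly6d, with the same number of each kind among their 10 leading genes. Bone marrow MP was 66.9% dendritic cell-like, 17.8% HSC-like and 5.93% lymphoid-primed progenitor-like, where 1378 of 1413 spleen MP cells were dendritic cell-like. Spleen DCP was 77.5% dendritic cell-like, where bone marrow DCP was 96.6% cycling cells. Of the 36 bone marrow MCP cells, 14 were mast cell or basophil progenitor-like, against 534 of 553 in the spleen. Cells of dendritic, T, B or mast cell classes together made up 57.6% of the spleen library (56.3 to 58.8%) and 1.18% of the bone marrow library (0.978 to 1.41%). They were 32.6% of spleen HSC-1 (501 of 1539 cells) and 0 of 5049 cells of bone marrow HSC-1, which allows a share of up to 0.0730%. The progenitor classes depend on the clustering resolution (0.8 here): HSC-like cells were 5.13% of the spleen library at 0.8 and 6.49% at 1.2. At 0.4 they were 20.8%, but 951 of those 1361 cells fell in a cluster with Pf4, Cavin2 and Itga2b among its leading genes. Cells of the lymphoid-primed name were 25.5%, 46.7% and 11.3% of the bone marrow library at 0.8, 0.4 and 1.2, and no multipotent class was found at 0.4. Dendritic cell-like cells (31.0% of the spleen library) and mast cell or basophil progenitor-like cells (11.6%) were the same at all 3. The authors' atlas-based labels, also in the deposited table, named 13.9% of spleen HSC-1 cells dendritic cells with high Cst3, 9.55% mast cells of neonatal muscle, and 75.8% of spleen LP cells thymic gamma-delta T cells. Transcripts of Kit, a receptor the sort selects on, were present in these clusters: 189 CPM (UMI counts scaled to the same total in each library or cluster) in spleen MP and 1307 in spleen MCP, against 316 in spleen HSC-1. Kit alone does not cover the gate, which also selects on Sca1, encoded by Ly6a. Without dendritic, T, B or mast cell classes, Ly6a stood at 3.70 CPM in spleen MEP and 114 in spleen HSC-1. In the bone marrow it stood at 6.0 and 108 CPM.

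**Figure D2:**
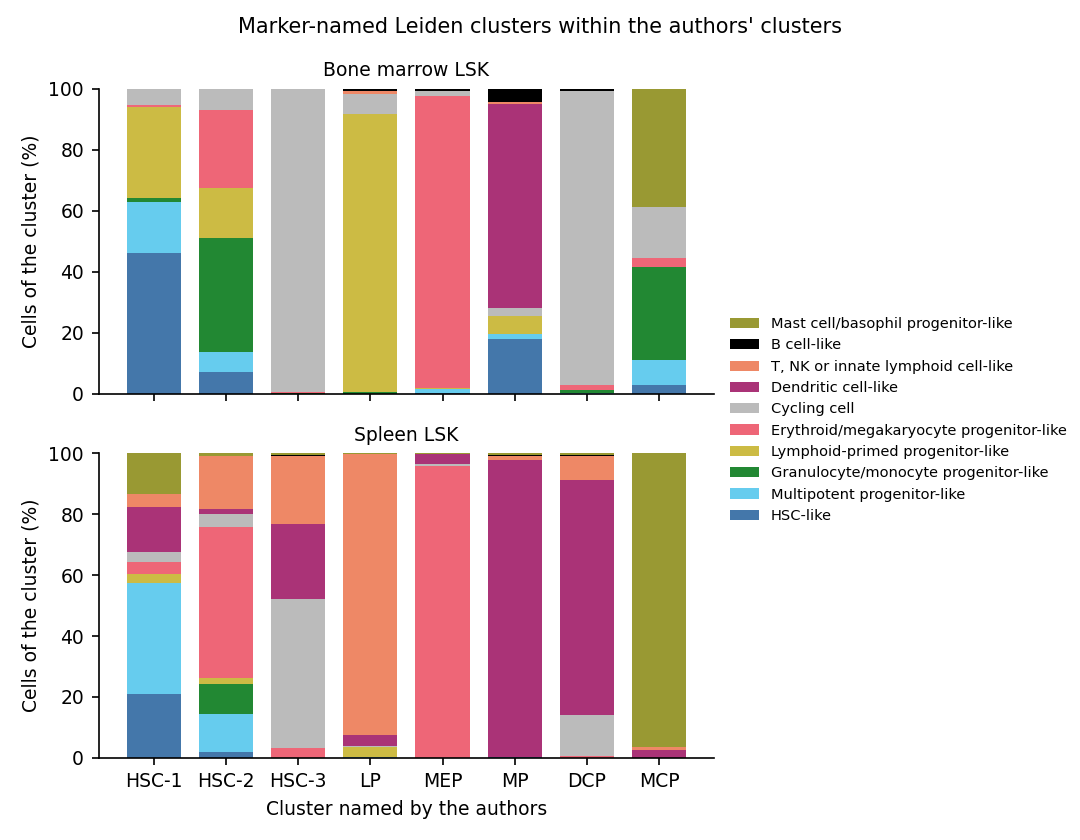
Share of the cells of each of the authors' clusters (x axis) that fall in each marker-named Leiden class (%, y axis), stacked, with bone marrow LSK above and spleen LSK under it. Of the 1413 spleen MP cells, 1378 are dendritic cell-like, and spleen LP is 92.4% T, NK or innate lymphoid cell-like.

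The next question was which genes differed between the LSK pools as a whole. Antigen presentation, mast cell and T-lineage genes were far higher in the spleen, and neutrophil granule and stem cell genes were far lower. Of 8644 genes with a mean of at least 10 CPM, 359 were at least 2-fold higher and 566 at least 2-fold lower in the spleen (a rule of size, with a pseudocount of 1 CPM). The median log2 ratio of these genes was −0.11, and list medians below are followed by their value relative to it. Scaling by trimmed mean of M values (TMM) moved that median to 0.10 and the counts to 541 higher and 355 lower, and centring on the median gene gave 433 and 452, so the balance of higher and lower genes rests on the scaling. It also rests on the makeup of the pools: with the authors' clusters weighted alike in both libraries, 190 genes were higher and 97 lower. Weighting each cell alike gave 378 and 349, and thinning to 3700 UMIs per cell gave 347 and 327. Thinning also left out the 1007 bone marrow and 672 spleen cells below that depth. Spleen MCP fell from 553 to 133 cells and bone marrow HSC-1 from 5049 to 4225, so the thinned values differ in makeup as well.

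Genes of mast cells stood at the top. Mcpt4, which encodes a chymase of mast cell granules (mm10 chromosome 14, 56059629 to 56062313), was at 0.597 CPM in the bone marrow and 206 in the spleen, 346-fold higher (257 to 476). Cma1 (287-fold) and Tpsb2 (299-fold), a second chymase and a tryptase, moved with it. MHC class II genes, whose products present peptides to T cells, formed the most abundant group: Cd74 (chromosome 18, 60803848 to 60812652) went from 129 to 5449 CPM, 42.2-fold higher (41.4 to 43.1), H2-Aa (chromosome 17, 34282744 to 34287823) from 72.0 to 2734 CPM, and H2-Eb1 from 53.9 to 2401 CPM. Ciita, which switches these genes on, stood at 5.63 and 129 CPM. Beside them were Cxcl9 (89.1 CPM in the spleen), an interferon-induced chemokine, and Dnase1l3 (117 CPM), both leading genes of spleen MP. The T-cell receptor constant genes Trbc1 (1.25 and 183 CPM) and Trbc2, the T-lineage regulator Tcf7 (0.949 and 65.8 CPM) and Ly6d (0.909 and 175 CPM), a gene of committed lymphoid progenitors, completed the 12 highest.

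Among the 12 lowest, 5 were genes of the granulocyte and monocyte path. Elane (chromosome 10, 79886247 to 79888215), which encodes neutrophil elastase, was at 358 CPM in the bone marrow and 11.0 in the spleen, 32.4-fold lower (30.4 to 34.6). Mpo (chromosome 11, 87793581 to 87804413), which encodes myeloperoxidase, was at 597 CPM (592 to 603) and 38.4 CPM (37.1 to 39.8), 15.5-fold lower. Ctsg (8.95-fold), Prtn3 (6.78-fold) and Ms4a3 (11.9-fold) moved with them. The stem cell regulators Hlf (chromosome 11, 90336536 to 90390895; 413 and 71.1 CPM, 5.81-fold lower) and Mecom (chromosome 3, 29951296 to 30548008; 103 and 16.8 CPM, 6.13-fold lower) followed, with the platelet chemokine Pf4 (6.06-fold lower), the fetal-type chromatin gene Hmga2 (5.46-fold), the glycosyltransferase Gcnt2 (5.33-fold), the inflammatory chemokine Ccl3 (6.46-fold) and Wfdc17 (6.38-fold).

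Lineage lists were then read to ask toward which fates the spleen pool leaned. Over all cells, stem cell genes and granulocyte-monocyte genes were lower. The joint list of erythroid and megakaryocyte genes and the lymphoid list each had members in both directions. Of 27 stem cell genes measured, 21 were lower by at least 1.5-fold and 1 higher (median log2 ratio −1.21, resampling range −1.79 to −0.93; −1.10 relative to all genes; percentile 0 among 10000 random lists matched on expression). Mecom (−2.55) and Hlf (−2.52) were lowest, Procr, the EPCR receptor of stem cells, stood at −1.17, Ly6a, which encodes Sca1, at 0.19, and Sult1a1 at 1.21. Of 24 granulocyte-monocyte genes, 13 were lower and 4 higher (median −0.81, −1.81 to −0.33; −0.70 relative). The regulators of this path were lower too: Cebpa, needed for the granulocyte-monocyte progenitor stage, stood at 29.3 and 9.87 CPM (2.97-fold lower) and Cebpb, which drives emergency granulopoiesis, at 53.1 and 29.1 CPM. Spi1, which encodes the myeloid and lymphoid regulator PU.1, stood at 167 and 147 CPM. The higher members included Irf8 (54.5 and 346 CPM), which drives dendritic cell and monocyte fate, and Csf2ra (16.4 and 31.3 CPM), a subunit of the GM-CSF receptor. Both peaked with the antigen-presenting genes: Irf8 was at 1311 CPM in spleen MP and 14.6 in spleen MEP.

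The joint list of erythroid and megakaryocyte genes went in both directions, and a separate list of erythroid cell markers, given below, had a median near that of all genes. Of 31 measured in the joint list, 12 were higher and 11 lower (median −0.35, −0.77 to 0.86, and −0.24 relative), with the red cell genes Car1 (134 and 1177 CPM) and Ermap (13.7 and 104 CPM) at the top and the platelet-lineage gene Pf4 (124 and 20.4 CPM) at the bottom. Gata1, the master regulator of red cell fate, was 3.84-fold higher over all cells (8.80 and 33.8 CPM) and level within MEP (78.9 and 79.9 CPM). Of 23 lymphoid progenitor genes, 11 were lower and 7 higher (median −0.46, −0.86 to 0.41; −0.36 relative): Flt3, the cytokine receptor of lymphoid-primed progenitors, stood at 281 and 87.8 CPM, Dntt at 165 and 78.0, and Mef2c at 494 and 127, while Ly6d and Il7r (6.79 and 62.7 CPM), the interleukin-7 receptor, were higher. Mast cell, basophil and eosinophil progenitor genes had 7 of 10 members higher (median 2.29, −0.37 to 4.50, and 2.40 relative), led by Mcpt4 and Fcer1a, with Ccl9 and Gata2 (152 and 88.8 CPM) lower. Without the cells of dendritic, T, B or mast cell classes, a removal that takes out mast cells themselves, 0 of 4 measured members were higher and 1 lower (median −0.51).

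Genes tied to suppressive myeloid cells, the cells that tumour-driven myelopoiesis is known for, were lower in the spleen LSK pool in 8 of 11 measured members and higher in 0 (median −1.21, −2.62 to −0.32; −1.10 relative). S100a8, an alarmin of neutrophils and their precursors, stood at 23.0 CPM in the bone marrow and 0.338 in the spleen, Wfdc17 at 159 and 24.9, and Hif1a (34.4 and 34.7 CPM) and Ncf1 were between the limits. Within clusters the difference was smaller. Without the cells of dendritic, T, B or mast cell classes, the list median was −0.10 in HSC-1 (−1.16 to 0.17, 1 of 11 higher and 3 lower). It was then −0.07 in HSC-2 (−1.44 to 0.19), −0.45 in HSC-3 and −0.47 in MEP. Only 2 mature neutrophil markers were abundant enough to measure, S100a8 and Csf3r (29.9 and 4.28 CPM), the G-CSF receptor, and both were lower.

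The series title names PERK, so the next question was whether spleen LSK cells carried more transcripts of the unfolded protein response, whose 3 sensors are PERK (Eif2ak3), IRE1 (Ern1) and ATF6 (Atf6). Over all cells, transcripts of PERK and ATF6 were level and those of IRE1 lower in the spleen. Without the cells of dendritic, T, B or mast cell classes all 3 were lower over the pool, in which MEP then gave 61.9% of spleen UMIs and 5.73% of bone marrow UMIs. Within HSC-1, HSC-2, HSC-3 and MEP the Eif2ak3 ratio was then 0.948, 0.885, 0.908 and 0.687, and each interval included 1. The MEP interval was wide (0.462 to 1.05), from 30 bone marrow UMIs. Ern1 was lower in each of these clusters (ratios 0.664, 0.668, 0.494 and 0.370, each interval under 1). Atf6 was lower in HSC-2 (0.758, 0.641 to 0.891), HSC-3 (0.635, 0.501 to 0.798) and MEP (0.746, 0.600 to 0.936). In HSC-1 the interval of the Atf6 ratio included 1. The PERK arm moved in 2 directions over all cells, with Asns and Mthfd2 higher and Atf4 and Ddit3 lower. Eif2ak3 (chromosome 6, 70844515 to 70905245) stood at 9.56 CPM in the bone marrow and 9.18 in the spleen, a ratio of 0.960 (0.867 to 1.07), and 0.683 (0.597 to 0.781) without the other classes. Atf6 (chromosome 1, 170704674 to 170867771) stood at 36.7 and 37.5 CPM (ratio 1.02, 0.970 to 1.07), and at 36.2 and 21.6 CPM without the other classes (0.596, 0.554 to 0.640). Ern1 (chromosome 11, 106394650 to 106487852) was 2.72-fold lower (37.0 and 13.6 CPM; 2.54 to 2.91). Atf4 (chromosome 15, 80255184 to 80257541), which encodes the transcription factor translated when PERK is active, stood at 190 and 123 CPM, 1.54-fold lower (1.51 to 1.58), and was lower in the spleen in each of the 7 clusters with at least 100 cells per library (log2 ratio −0.19 in MEP to −0.90 in MP). Ddit3 (chromosome 10, 127290774 to 127296288), which encodes CHOP, stood at 40.0 and 23.0 CPM (log2 ratio −0.77). Xbp1 (chromosome 11, 5520659 to 5525893), whose messenger RNA IRE1 splices, stood at 58.5 and 47.5 CPM, and Hspa5 (chromosome 2, 34771970 to 34777547), which encodes the chaperone BiP, at 327 and 336 CPM. Counts from the 3′ end do not show splicing of Xbp1, phosphorylation of PERK or translation of Atf4.

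Of 35 PERK, ATF4 and CHOP genes measured, 5 were at least 1.5-fold higher, 6 lower and 24 between (median 0.23, 0.06 to 0.32; 0.34 relative to all genes; percentile 99.7 among the random lists). Asns, which makes asparagine, was at 12.1 and 66.2 CPM, Mthfd2, a mitochondrial folate enzyme, at 16.7 and 41.1 CPM, and Slc7a5, an amino acid carrier, had a log2 ratio of 0.76. Vldlr (45.9 and 7.30 CPM), Cebpd (19.9 and 5.14 CPM) and Ppp1r15a (142 and 67.9 CPM), which encodes the phosphatase subunit that ends the PERK response, were lower. With clusters weighted alike the median was −0.08, and with each cell weighted alike −0.012. Asns was concentrated in MEP, at 106 CPM in the bone marrow and 171 in the spleen, and stood at 2.71 and 4.05 CPM in HSC-1. Summed over its members, the list was at 2851 and 2899 CPM in MEP, 1881 and 1690 in HSC-1, and 2038 and 1557 in MP. The ATF6 chaperone list had 3 of 21 members higher and 0 lower (median 0.03, −0.08 to 0.32; 0.14 relative), with Sdf2l1, an ER-resident cofactor of BiP, at 13.6 and 38.5 CPM, Atf6b at a log2 ratio of 0.73, and the calcium-binding chaperone Calr (577 and 448 CPM) and Sel1l, of the ER degradation machinery, slightly lower. The IRE1 and XBP1 list had 0 of 26 members higher and 4 lower (median −0.04, −0.26 to 0.20; 0.07 relative), among them Dnajb9 (45.0 and 23.2 CPM), a typical XBP1 target, with Ssr2 (0.54) and Derl2 (0.44) highest. The IRE1 and XBP1 median lies between 0 and the median of all genes, so its sign depends on the scaling. Within HSC-2 without the other classes all 3 lists were lower, in the order above at −0.22 (−0.31 to −0.04), −0.25 (−0.33 to −0.10) and −0.16 (−0.25 to −0.10). These HSC-2 cells still differed in makeup. Granulocyte-monocyte progenitor-like cells were 803 of 2147 in the bone marrow and 73 of 589 in the spleen. Erythroid or megakaryocyte progenitor-like cells were 552 and 366. Whether this accounts for the lower lists was not tested. Within HSC-1, HSC-3 and MEP the ranges of the 3 lists, without the other classes, included 0. With all cells kept, the PERK, ATF4 and CHOP list was at −0.49 in MP (16 of 35 lower, 2 higher) and 0.15 in LP (0.03 to 0.25). Relative to all genes of the same cluster, these medians were −0.24 in MP and 0.11 in LP. Both clusters hold different cells in the 2 tissues.

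The authors' deposited table also gives an ER stress score for each cell. That score averaged 0.0743 ± 0.0324 (SD over cells) in the bone marrow and 0.114 ± 0.0457 in the spleen, a difference of 0.0393, and its mean was higher in the spleen in 7 of the 8 clusters. In HSC-1 it was 0.0687 ± 0.0310 and 0.0963 ± 0.0432, in MEP 0.0896 and 0.144, in MP 0.0892 and 0.138, and in MCP 0.0950 and 0.0938. The table holds the same values for all 16634 cells in a column named for the GO term of the response to ER stress; the genes of that term are not given in the sources used here, so the score was not recomputed from the counts. The total per cell in the authors' SCT assay, a depth-adjusted count, had a median of 5990 in the bone marrow and 9978 in the spleen, which are close to the median UMIs of each library. A score of the 3 fixed unfolded protein response lists was therefore computed at 3 scalings. With each library scaled to its own median depth, the spleen minus bone marrow difference in the HSC-1 median was 0.0433; with both scaled to 1 total it was 0.0094; with both thinned to 3700 UMIs per cell it was 0.00046. In MEP the differences were 0.132, 0.066 and 0.0128. After thinning, the difference was 0.00438 over all cells, 0.0121 in DCP and negative in HSC-2 (−0.00708), HSC-3 (−0.00349), LP (−0.00579), MCP (−0.0193, from 20 and 133 cells) and MP (−0.00459, with a difference in means of 0.00115). Of the other deposited scores, the stemness score averaged 0.0713 ± 0.249 and 0.261 ± 0.391, highest in MEP (0.498 and 1.01) and lowest in bone marrow HSC-1 (−0.0694, and 0.0345 in spleen HSC-1). The myeloid score averaged 0.0499 and 0.0554, with 0.177 and 0.0294 in HSC-2 and 0.194 and 0.416 in MP, and the erythroid score 0.0639 and 0.0845.

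**Figure D3:**
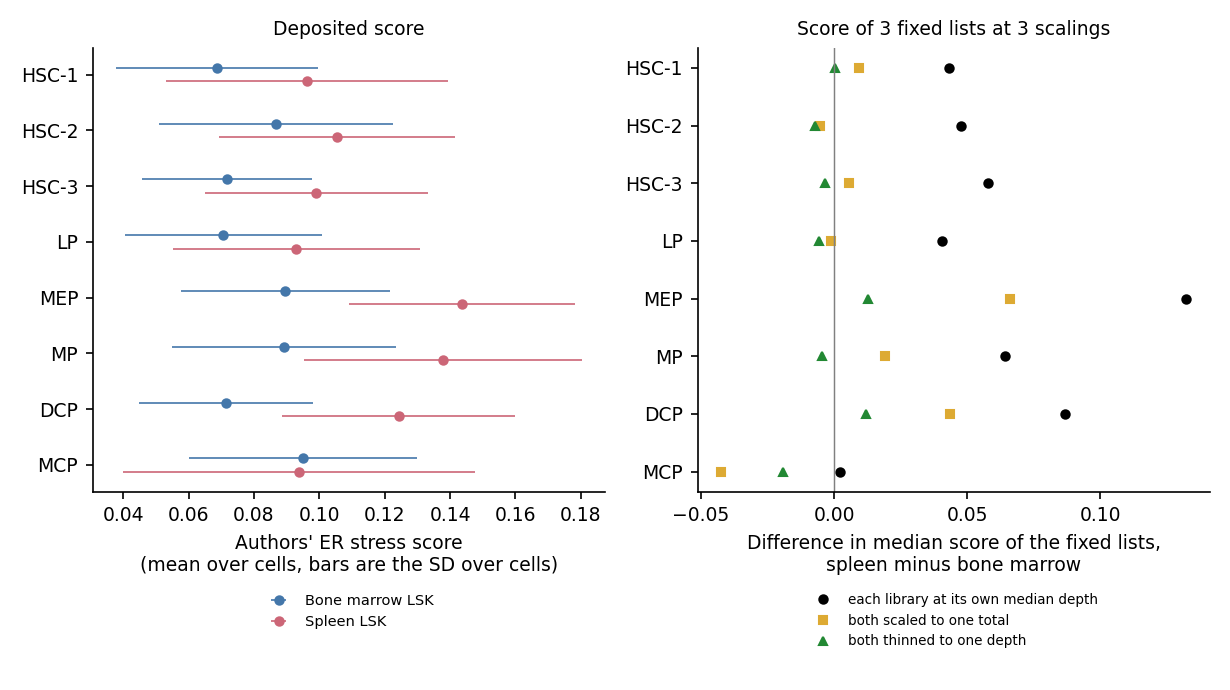
Left, mean of the authors' deposited ER stress score per cluster (x axis, score units; bars are the SD over cells) in bone marrow and spleen LSK cells; right, spleen minus bone marrow difference in the median score of 3 fixed unfolded protein response lists (x axis, score units) at 3 scalings. The deposited score is higher in the spleen in 7 of 8 clusters, and the HSC-1 difference of the fixed lists is 0.0433 at each library's own depth and 0.00046 after thinning to 1 depth.

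Cluster HSC-1 was read next, to ask how its spleen cells differed from those of the bone marrow. Quiescence genes were lower with and without the cells of other classes, the stem cell list was lower only with them, and the 3 unfolded protein response lists sat near 0. The 1539 spleen cells of this cluster include the 501 of dendritic, T, B or mast cell classes described above, so values without them (1038 cells, against all 5049 of the bone marrow) are given beside. These still differ in makeup: 321 of the 1038 are HSC-like, 563 multipotent progenitor-like and 46 of the lymphoid-primed class, against 2329, 840 and 1504 of the 5049. The PERK, ATF4 and CHOP list had a median of 0.02 (0 of 31 members higher, 3 lower) and −0.04 (−0.15 to 0.04) without the other classes, the ATF6 list 0.11 and 0.02, and the IRE1 and XBP1 list 0.04 and −0.03. Atf4 was at 207 and 123 CPM (log2 ratio −0.75, and −0.73 without the other classes), Ddit3 at 44.5 and 29.5 CPM (−0.57 and −0.45), Ern1 at 49.9 and 27.8 CPM (−0.82 and −0.58), and Hspa5 at 307 and 304 CPM (−0.02 and −0.23). Eif2ak3 was at 9.26 and 9.39 CPM (ratio 1.01, 0.797 to 1.28; 0.948, 0.711 to 1.25, without the other classes).

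The stem cell list in HSC-1 had 11 of 31 members lower and 1 higher (median −0.40), and −0.01 (1 of 32 higher, 1 lower) without the other classes. Hlf was lower either way: 674 and 334 CPM (2.02-fold lower, 1.95 to 2.09), and 468 CPM in the spleen without the other classes. Quiescence genes kept their lower median, at −0.40 (7 of 17 lower, 0 higher) and −0.41 (−0.64 to −0.14; 6 of 17 lower) without the other classes. Egr1, which holds stem cells in quiescence and is also induced by cell handling, was at 634 and 200 CPM without them. Respiratory chain genes had medians of 0.26 (4 of 56 higher, 0 lower) and 0.17 (0.12 to 0.22; 0 of 56 higher by 1.5-fold) without the other classes, and ribosome biogenesis and MYC target genes at 0.13 and 0.24 (0.14 to 0.35). G2 and M phase genes had medians of −0.07 (2 of 41 higher, 7 lower) and −0.36 (10 of 40 lower, 0 higher) without the other classes, and S phase genes −0.26 and −0.18. Phase calls put 12.5% and 13.6% of all HSC-1 cells in G2 or M phase. Lymphoid progenitor genes had medians of −0.17 (−0.43 to 0.49, with 4 of 22 higher and 5 lower) and −0.34 (−0.45 to −0.23, with 2 of 19 higher and 5 lower) without the other classes. Flt3 had a log2 ratio of −0.97 and Dntt of −1.55 in all HSC-1 cells, and −0.98 and −1.875 without the other classes. The granulocyte-monocyte list had a median of 0.11 (7 of 22 higher, 6 lower) and −0.03 without the other classes. Mpo was at 102 and 26.8 CPM (3.83-fold lower, 3.39 to 4.33), and Elane at 512 UMIs (19.3 CPM) against 3 UMIs (0.276 CPM, 0.0569 to 0.807); the 0.101 UMIs of Elane per bone marrow cell compare with 0.0901 in bone marrow MEP, so free RNA is not excluded for Elane here. MHC class II genes had a median of 2.72, and 0.27 without the other classes, with Cd74 then at 35.0 and 82.7 CPM. Kit was level (319 and 316 CPM).

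**Figure D4:**
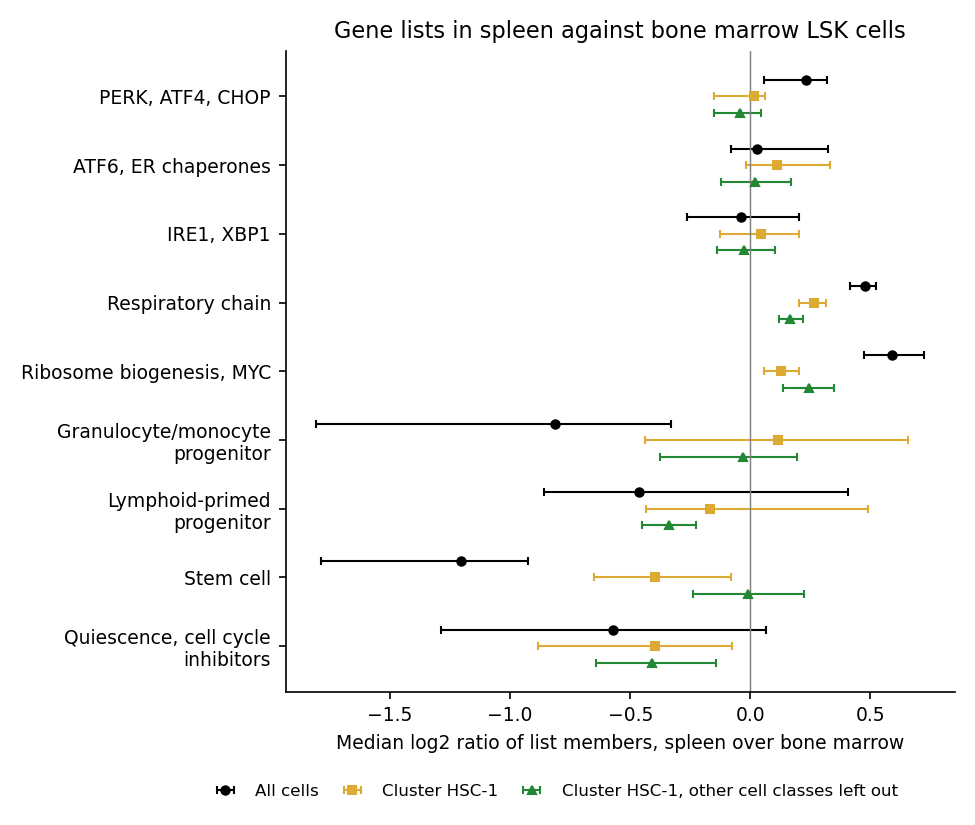
Median log2 ratio, spleen over bone marrow (x axis), of 9 gene lists (y axis) over all cells, in cluster HSC-1, and in HSC-1 without cells of dendritic, T, B or mast cell classes, with bars for the 95% range over 1000 resamplings of list members. In HSC-1 the PERK, ATF4 and CHOP list lies at 0.02 and −0.04, and the stem cell list moves from −0.40 to −0.01 when the other classes are left out.

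The other clusters were read for whether the same genes differ within them. Without the other classes, CPM of Elane, Mpo and Ctsg were lower and those of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 higher in the spleen in HSC-1, HSC-2, HSC-3 and MEP. Free RNA was not removed from these values: Cd74 then stood at 0.598 UMIs per cell in spleen HSC-1, 0.552 in HSC-2, 0.711 in HSC-3 and 1.11 in the erythroid cluster MEP, so free RNA is not excluded for Cd74 in these clusters. Elane in HSC-2, at 11.8 UMIs per bone marrow cell and 1.56 per spleen cell, stood far above the 0.0901 of bone marrow MEP. Mpo and Ctsg stood at 0.539 and 0.184 UMIs per cell in bone marrow HSC-1, against 0.341 and 0.141 in bone marrow MEP. Free RNA is thus not excluded for Elane, Mpo and Ctsg in HSC-1 and MEP. In HSC-2, Elane was at 1272 and 104 CPM, Mpo at 1788 and 282, and S100a8 at 53.4 and 0.338, while Trbc1, Trbc2 and Ly6d were highest; 17.6% of spleen HSC-2 cells were T, NK or innate lymphoid cell-like, and none of bone marrow HSC-2. In HSC-3, DCP and MEP, Cd74, H2-Aa and H2-Eb1 were the 3 highest genes, with Cd74 at 13.4 and 4050 CPM in HSC-3, 8.69 and 14141 in DCP, and 5.72 and 208 in MEP. Without the other classes, which were 47.8% of spleen HSC-3 and 86.1% of spleen DCP, Cd74 was at 13.4 and 43.0 CPM in HSC-3 (3.21-fold higher) and 5.76 and 31.2 in MEP (5.42-fold). The MHC class II list then had a median of 0.36 in HSC-2 (4 of 9 higher, 0 lower), 0.12 in HSC-3 (4 of 9 higher, 2 lower) and 0.74 in MEP (3 of 5 higher, 1 lower). Among granule genes, Prtn3 in HSC-1 then had a ratio of 0.878 (0.849 to 0.908) and Ms4a3 0.917 (0.610 to 1.35), and Ms4a3 was 1.59-fold higher in HSC-3. Ccl3, Ccl4 and Mpo were the 3 lowest in HSC-3 and DCP, and Hlf, Adgrl4 and Rgs1 in MEP. In LP, Ly6d (4.57 and 1716 CPM), the interleukin-2 receptor gene Il2ra and the granzyme gene Gzma were highest, and Nkx2-3, Wfdc17 and Mecom lowest. In MP, Cxcl9 (37.5 and 406 CPM), the inflammasome gene Mefv and Cd8a were highest, and Hlf (249 and 2.13 CPM), Ctla2a and Ccl3 lowest. At equal depth, 85.9% of spleen LP cells had a UMI of Trbc1 (88.5% unthinned), against 2.13% of spleen MEP cells (7.41% unthinned; median UMIs 7899 in LP and 36084 in MEP), which serves as a level of free RNA.

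The cell state lists were read for growth and cycling. Mitochondrial and biosynthetic genes were higher in the spleen pool, and the medians of cycling genes differed little over all cells but not within MEP and MP, which hold different cells in the 2 tissues. Of 56 respiratory chain genes, 13 were higher and 0 lower (median 0.48, 0.42 to 0.52; 0.59 relative), from Cycs (63.4 and 135 CPM), which encodes cytochrome c, and Atp5g1 (256 and 539 CPM) down to Ndufa6 (0.07) and Uqcrh (−0.04). Of 36 ribosome biogenesis and MYC target genes, 19 were higher and 0 lower (median 0.59, 0.47 to 0.72; 0.70 relative), with the mitochondrial chaperone Hspd1 (225 and 546 CPM) and the spermidine synthase gene Srm (64.8 and 155 CPM) highest, and Mcm4 and Myc itself (81.0 and 82.8 CPM) lowest. With clusters weighted alike, these medians were 0.24 and 0.11. Summed over its members, the ribosome biogenesis and MYC list was lower in spleen MP (5391 and 4625 CPM), DCP (6381 and 5505 CPM) and MCP (6012 and 4225 CPM), and higher in the other clusters. Glycolysis and hypoxia genes had 3 of 22 members higher and 8 lower (median −0.03; 0.08 relative; 0.17 under TMM scaling), with Ldha (261 and 503 CPM) and Eno1 higher and the hypoxia-induced Egln3 and Bnip3 lower. Quiescence genes had 7 of 17 members lower and 2 higher (median −0.57, −1.29 to 0.06; −0.46 relative; −1.01 without the other classes, with 15 of 17 lower), with Egr1 (348 and 92.3 CPM) and Gfi1 lowest and the antiproliferative genes Btg1 and Btg2 highest. S phase genes had 2 of 43 members higher and 0 lower (median −0.13; −0.02 relative; 0.08 under TMM scaling; 0.29 without the other classes, with 9 of 43 higher), with Rrm2 and Nasp highest and Dtl and Brip1 lowest. G2 and M phase genes had 4 of 51 higher and 2 lower (median 0.04; 0.15 relative), with Ube2c (95.9 and 217 CPM) and Tubb4b highest and Gas2l3 and Hjurp lowest. Mki67 stood at 457 and 412 CPM. Phase calls on thinned cells put 1729 of 9081 bone marrow cells (18.2 to 19.9%) and 790 of 5874 spleen cells (12.6 to 14.3%) in S phase, and 28.8% and 28.9% in G2 or M phase (24.5% and 24.3% without thinning). In MEP, G2 or M phase calls were 31.7% (26.6 to 37.1%) and 60.9% (57.6 to 64.2%); free RNA of cycling cells was not removed before these calls. G2 and M phase genes were higher in MEP in 31 of 50 members and lower in 0 (median 0.79, and 0.78 without the other classes), where the authors' second annotation named 69.1% of spleen and 19.3% of bone marrow cells Ery-3. They were lower in MP in 47 of 48 (median −2.05). S phase genes were lower in MP in 31 of 33 (−1.64) and in DCP in 23 of 37 (−0.77).

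Over all cells, MHC class II genes were higher, and the other response lists had medians from −0.41 to 0.06. Inflammatory and NF-kB genes had 7 of 21 members lower and 3 higher (median −0.31; −0.20 relative), with the chemokines Ccl3 (106 and 16.4 CPM) and Ccl4 lowest and Traf1 (6.13 and 30.9 CPM) and Nfkbia, the inhibitor that NF-kB itself induces, highest. Interferon response genes had 11 of 27 lower and 5 higher (median −0.17; −0.06 relative; 0.05 under TMM scaling), with Ifi203 and Rsad2 lowest and Phf11b (10.3 and 25.7 CPM) among the highest. MHC class II genes had 10 of 11 higher and 0 lower (median 3.03, 1.58 to 5.23; 3.13 relative), from H2-Eb1 and Cd74 down to H2-DMa (172 and 374 CPM) and H2-Ob (0.09). Immediate early genes, which also respond to tissue dissociation, had 9 of 25 lower and 6 higher (median −0.24; −0.13 relative), with Fosl2 and Rhob (120 and 29.9 CPM) lowest and Ier5 and the heat shock gene Hsph1 highest. Adhesion and homing genes had 10 of 22 lower and 4 higher (median −0.41; −0.31 relative), with the endothelial and stem cell receptor Robo4 and the egress receptor S1pr1 (27.9 and 5.11 CPM) lowest and the integrin subunits Itgb2 and Itgb7 highest. Apoptosis and p53 target genes had 5 of 20 lower and 3 higher (median 0.06; 0.17 relative), with Cdkn1a and Sesn1 lowest and Bax (47.6 and 120 CPM) and Aen highest. Genes of the sort gate had 3 of 7 lower and 0 higher (median −0.28; −0.17 relative; 0.14 under TMM scaling; −1.20 without the other classes, with 5 of 7 lower), with Cd34 (359 and 102 CPM) and Flt3 lowest and Cd48 and Ly6a (70.5 and 80.6 CPM) highest.

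Markers of cell types outside the gate were measured beside them. T and NK cell markers had 5 of 7 members higher and 0 lower (median 4.92, 0.42 to 5.33; 5.02 relative), with Nkg7 and Gata3 lowest. Mast cell and basophil markers had 7 of 7 higher (median 4.50, 2.74 to 6.07; 4.61 relative), from Cma1 and Tpsb2 down to Il1rl1 (3.69 and 30.3 CPM) and Hdc. Monocyte, macrophage and dendritic cell markers had 4 of 10 higher and 2 lower (median 0.41; 0.52 relative; −0.08 with mitochondrial, ribosomal protein and the 50 most abundant genes left out of the scaling total), with Batf3 (1.55 and 61.0 CPM) and Xcr1 (2.54 and 77.7 CPM), genes of cross-presenting dendritic cells, highest and Ly6c2 and Flt3 lowest. B cell markers had 2 of 6 higher and 1 lower (median −0.06; 0.05 relative; 0.14 under TMM scaling): Cd74 and Ly6d, which dendritic and lymphoid cells also express, were the higher ones, Cd79b (40.2 and 16.5 CPM) was lower and Ighm stood at −0.37. Megakaryocyte and platelet markers were lower in 5 of 5 (median −1.25; −1.14 relative), among them Pf4, Itga2b and Gp9. Erythroid cell markers had 1 of 5 higher and 1 lower (median −0.13; −0.03 relative; 0.07 under TMM scaling), with Fech and Bpgm highest and Hemgn and Car2 lowest. Stroma and endothelium markers had 2 of 4 lower (median −0.66; −0.56 relative), with Emcn and Pdgfrb lowest and Pecam1 and Vim between the limits. Of the hepatocyte and hepatoma markers, only Krt18 (85.5 and 32.3 CPM) and Trf (42.1 and 23.4 CPM) were measured, and both were lower; spleen HSC-1 itself listed Krt18 among its 10 leading genes.

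When all cells of the dendritic, T, B and mast cell classes were left out (9969 and 2778 cells), MHC class II genes had a median of −0.54 (−1.39 to 0.86; 3 of 9 higher, 4 lower; Cd74 1.85-fold and H2-Eb1 2.46-fold higher), granulocyte-monocyte genes −1.32 (19 of 23 lower, 0 higher), stem cell genes −1.15, respiratory chain genes 0.63 (31 of 56 higher) and ribosome biogenesis and MYC target genes 1.05 (33 of 36 higher). Lymphoid progenitor genes were lower in 16 of 19 members and higher in 0 (median −1.29), inflammatory and NF-kB genes lower in 12 of 17 (−1.14), interferon response genes in 16 of 26 (−0.70), immediate early genes in 16 of 24 (−1.19), adhesion and homing genes in 12 of 22 (−0.75) and apoptosis and p53 target genes in 9 of 19 (−0.57). These sums weight MEP at 61.9% of spleen and 5.73% of bone marrow UMIs. Within HSC-1 without the other classes the same medians were −0.34, −0.17, 0.09, −0.15, 0.11 and −0.09. The removal also took out 667 of 693 spleen LP cells and 12 of 770 bone marrow LP cells. The lower lymphoid median over the remaining pool is therefore fixed in part by the removal itself. The same holds for the MHC class II median, since the dendritic cell markers include Cd74, H2-Aa and H2-Ab1. The PERK, ATF4 and CHOP list then had 14 of 34 members higher and 6 lower (median 0.49), with 861 of the 2778 remaining spleen cells in MEP, where Asns and the sum of the list were highest. Atf4 was still lower, at 190 and 133 CPM.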

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

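Chosen only after the results were seen were the settings without MP and MCP together, without the cells of dendritic, T, B or mast cell classes, and with HSC-1 limited to cells also labelled HSC-1 in the authors' second annotation; the other settings were planned. No paired analysis was possible because each tissue has 1 library. Within 1.5 times the number of genes found were 19 of 30 counts of genes; of list medians over all cells, 371 stayed within their resampling range, 50 moved and 7 reversed; within clusters, 647, 48 and 6; of gene ratios, 635, 1084 and 10; of shares, 34 stayed within their interval and 40 moved; of phase shares, 6 and 2. The numbers of genes at least 2-fold higher and lower were 541 and 355 with TMM factors (which shift every ratio, so here construction gives the cause), 378 and 349 as a mean over cells, 347 and 327 thinned, 190 and 97 with clusters weighted alike, 727 and 1123 with a floor of 1 CPM, 116 and 155 with a floor of 50 CPM (more and fewer genes measured), and 482 and 890 without the other classes. With clusters weighted alike, 161 of the higher and 88 of the lower genes were the same genes as in the comparison of all cells. Centring shifts every ratio by 1 constant as well, and sign changes under these 2 settings are among the reversed medians. For the other values that follow, the cause was not tested. Leaving out the other classes, however, fixes in part the values of their own genes. The markers that named these classes include Cd74, H2-Aa, H2-Ab1, Irf8 and Hdc. MEP then also gave 61.9% of spleen and 5.73% of bone marrow UMIs. The PERK, ATF4 and CHOP list had a median of 0.44 with TMM, 0.34 centred, −0.012 as a mean over cells, −0.084 with clusters weighted alike, 0.32 without MP and MCP and 0.49 without the other classes. Granulocyte-monocyte genes had −0.11 as a mean over cells and −0.30 with clusters weighted alike, and stem cell genes −0.84 thinned and −0.45 weighted alike. S phase genes had 0.075 with TMM, 0.094 without MP, 0.11 without MP and MCP and 0.29 without the other classes. MHC class II genes had −0.54 without the other classes. In DCP, centring gave 0.076 for ribosome biogenesis and MYC targets and 0.013 for G2 and M phase genes. In HSC-1, centring gave 0.083 for the PERK, ATF4 and CHOP list, the second annotation −0.031 for the ATF6 list and 0.058 for platelet genes, and leaving out the other classes 0.077 for platelet genes. Leaving out the other classes gave −0.054 for B cell markers in HSC-2 and −0.029 for G2 and M phase genes in HSC-3, and reversed Irf8 (−1.63), Sult1a1 (−1.54), Il7r (−0.33), Traf1 (−0.81), Phf11b (−1.33), H2-DMa (−0.54), Ier5 (−0.54), Itgb7 (−0.40), Itgb2 (−0.41) and Hdc (−0.97). G2 or M phase shares were 24.5% and 24.3% without thinning, and thinning gave 1718 and 1637 median genes per cell. Leaving out the other classes moved the ratio of Eif2ak3 from 0.960 to 0.683 and of Atf6 from 1.02 to 0.596. Depth limits genes under 10 CPM.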

Other observations

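Chosen only after the result was seen were the tests of free RNA in the MP cells, of cluster makeup behind the authors' score, of the makeup of Leiden classes and of free RNA in the bone marrow droplets; the other 4 tests were set beforehand. The first of these was first read against spleen HSC-1, where MP stood 4.79 times as high, between the bounds of 2 and 10, and the second with clusters weighted alike, where 76.5% of the difference was left, between the bounds of 50 and 80; both were then replaced, with these values known, by the tests given here. The test of free RNA in the bone marrow droplets was first read as the summed CPM in bone marrow HSC-2 over HSC-1 (7.66 times), and replaced because these genes lead HSC-2. The estimate of free Kit RNA was also added after the results.

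Deposited pseudotime, given for 5741 bone marrow and 4391 spleen cells, averaged 7.08 ± 3.47 (SD over cells) and 11.3 ± 4.52. In HSC-1 it averaged 5.74 and 6.78, in LP 11.0 and 12.8, in MP 16.5 and 15.8, and in MCP 9.58 and 9.60. The authors' second annotation named 29.2% of spleen cells and 0.625% of bone marrow cells Mono-3, 8.65% and 0.178% Cd3d-positive T cells, 9.59% and 0.684% Ery-3, 5.65% and 0.0694% Ba-4, and 28.0% and 78.2% HSC-1. The labels Neu-1 and Neu-3 were scarcer in the spleen: Neu-1 held 0.962% against 2.61%, and Neu-3 0.122% against 1.22%.

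Spleen MP cells carry dendritic cell genes although the sort selects progenitors. The summed CPM of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 in MP (47925) was 90.2 times that in MEP (531), the lowest spleen cluster, against median UMIs per cell of 10725 and 36084. These genes are among the leading genes of MP, so a higher level there was given in advance. Only the size of the ratio bears on free RNA of dendritic cells, and it argues only against free RNA that reached all droplets alike. Scrublet called 1.27% of spleen MP cells doublets. That does not exclude doublets, since a mixture that makes up 21.6% of a library can pass as a cell type of its own. Kit in MP stood at 59.8% of its level in spleen HSC-1 (58.1% with the other classes left out of HSC-1). As a sum over the cluster, it argues against MP cells that all lack Kit, but not against a part of them lacking it. Free RNA would give 29.3 of the 189 CPM of Kit in MP (15.5%) if all Hlf, Trbc1, Car1 and Mcpt4 counts there were free and came with Kit as in the other 7 clusters. A candidate explanation left open is a Kit-positive, dendritic-lineage precursor or dendritic cell population inside the spleen gate, from tissue, sort setting or enrichment step, which this design cannot separate.

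The authors' ER stress score is higher in spleen cells. A makeup of clusters that differs is argued against as the whole cause, since the median difference within clusters was 69.7% of that over all cells, though a different mixture of cells inside each cluster stays open. Scaling of each library to its own depth could account for it: in the fixed lists, 1.06% of the HSC-1 difference was left after thinning to 1 depth, and 21.7% with both libraries at 1 total. That test used stand-in lists, whose score had a Pearson r with the authors' score across HSC-1 cells of 0.442 in the bone marrow and 0.574 in the spleen (cells are not replicates). Higher protein-level activity of PERK in spleen cells was not measured here and stays open.

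Neutrophil granule genes are lower in the spleen library. Over all cells, Elane, Mpo, Ctsg, Prtn3 and Ms4a3 had a median log2 ratio of −3.35, and without the other cell classes −2.73 (−2.21 within HSC-2, −1.12 within HSC-1, −0.93 within HSC-3 and −2.74 within MEP). Bone marrow MEP then held 0.0901 UMIs of Elane, 0.341 of Mpo and 0.141 of Ctsg per cell. Bone marrow HSC-1 was close to that, at 0.101, 0.539 and 0.184, though Prtn3 stood at 3.38 against 0.992 in MEP. Free RNA is therefore not excluded for the ratios within MEP and, Prtn3 aside, within HSC-1. Makeup of the authors' clusters is argued against as the whole cause by −2.29 with these weighted alike. In bone marrow cells of equal depth, each gene stood higher in the cells with most UMIs of the other 4 than in the rest (median ratio 22.8, from 3.18 for Prtn3 to 76.5 for Elane). These genes lead HSC-2 together, so a higher level was given in advance. The size of the ratio argues only against free RNA spread alike over all droplets as the whole source. How much of the RNA in the remaining cells was free was not tested. A different mixture inside the authors' clusters could account for most of the lower level of granule genes. With the marker-named Leiden classes weighted alike the median was −0.81 (−0.20 at resolution 0.4 and −0.51 at 1.2). Bone marrow HSC-2 held 37.4% granulocyte-monocyte progenitor-like cells against 9.91% in spleen HSC-2. The Leiden classes were, however, formed in part from the same genes. Whether such a mixture comes from tissue, sort or library is confounded here.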
